A study of Mus musculus with 24 samples.

How the data were processed

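Liver RNA from male C57Bl/6 mice was measured on the Affymetrix MoGene 1.0 ST array, which reads each gene through a set of short probes. The 24 arrays are labelled as 1 mouse each. Per the labels, the mice fell into 4 groups of 6 that combined 2 diets (menhaden fish oil or lard) with 2 kinds of bacterial status (conventional, or germ-free, meaning raised without microbes). Per the labels' protocols, both diets supplied 45% of energy as fat and were fed for 11 weeks, the mice were given as 11 weeks of age, which conflicts with 11 weeks of feeding unless it began at birth, so age at sampling is uncertain, they were fasted for 4 hours before the livers were taken, and 250 ng of total RNA entered each labelling reaction.

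The authors' values are log2 signals made by RMA, per the file headers and the submitters' processing notes. Per the file headers, the authors ran RMA at gene level in Affymetrix Expression Console (apt engine 1.1.2800.28061, array library r4) over the 24 arrays in 1 run, with background correction, quantile normalization and median polish, and the deposited log2 values were not centred by gene or array. Quantile normalization gives every array nearly the same distribution, so a change shared by most genes cannot be seen in these values, and median polish can blend members of gene families that share probe sequence. The 2 log2 tables held the same values to within 0.005, and the table with more decimals was used. A genome build is not given in the sources used here, so no coordinates are reported.

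Of 35556 probe sets, 21789 were paired with exactly 1 gene symbol in the platform annotation, 1621 with several and 12146 with none listed there; 21698 of the single-symbol probe sets were matched to a current symbol by Entrez identifier. Where a gene had more than 1 probe set (999 genes), the probe set with the highest mean was used, which left 19938 genes, with no filter on level. Arrays give no read depth, and the number of mice limits the precision. Array medians lay between 6.445 and 6.623 on the log2 scale, and the mean correlation of an array with the others of its group lay between 0.9837 and 0.9958. The labels number the mice but say nothing of litters, cages or array batches.

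Before any test, the mice of each group were compared pairwise over the 300 most variable probe sets. Fish oil germ-free mice 3 and 4 differed with an SD of 0.104, while the next closest of the 60 pairs differed with an SD of 0.318 and the most distant with 1.45. They differed by less than any other pair within a group and could be 1 liver measured on 2 arrays, so their mean was counted as 1 sample, which left 23 samples and n = 5 in that group. This departs from the written plan, which counted 24 samples; the fit with 24 was added as an alternative.

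Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) on 4 group means with 1 pooled spread per gene. The contrasts were fish oil minus lard in conventional and in germ-free mice, germ-free minus conventional on each diet, and the difference between the 2 diet effects. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Values after ± are the standard error (SE) of a log2 difference unless given as SD. Limma's camera, with a preset inter-gene correlation of 0.01, tested 36 gene lists of pathways and cell type markers; camera with an estimated correlation and limma's fry were alternatives. The groups, contrasts, lists, alternatives and naming rule were fixed before the data were examined. The rule named the 6 highest and 6 lowest called genes of each contrast and up to 3 called genes with the smallest p from each of the 6 lists with the smallest p in the 4 pairwise contrasts. It also took 8 fixed genes, of which 6 had a value; the others are not reported here. Unnamed transcripts were passed over. Other genes mentioned are members of the lists, or were chosen after their values were seen (Nnt, Wdfy1, Hsph1, Dbp, Arntl, Per1, Saa1, Lcn2 and the genes that separated every germ-free from every conventional mouse).

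The alternatives written down with them were a filter on level, all probe sets or the mean of a gene's probe sets, equal array medians, a second quantile normalization, a trended and robust variance model, array weights, a fold threshold of 1.5, the other deposited table, the mouse number as a block, each comparison fitted on its own 2 groups, and each mouse left out in turn. Alternatives added after the data were seen were the 24 arrays as separate samples, a clock index (Dbp minus Arntl) as a covariate, the 75th percentile of each array as a covariate, fish oil conventional mice 5 and 6 left out, and germ-free mice 5 and 6 of both diets left out. Each count was also recomputed for up to 100 other splits of the same mice. The procedure was tested on simulated data with independent noise and the pooled spread of each of the 19938 genes. Of genes changed 1.5-fold, 94% were recovered for fish oil against lard in conventional mice, 95.5% for the same diets in germ-free mice, 91% for germ-free against conventional mice on lard, 83.6% on fish oil and 59.7% for the difference of the diet effects. The simulation gave all groups the same spread. In the data the fish oil conventional mice varied more (median SD 0.211 against 0.111 to 0.119). Recovery in the contrasts that use that group may therefore be overstated. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.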

Results

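Liver gene expression was measured by array in mice fed fish oil or lard that were either conventional or germ-free, with 6 arrays per group, and 19938 genes were tested. Fish oil germ-free mice 3 and 4 differed by less than any other pair of mice within a group and were counted as 1 sample, so n = 5 in that group and n = 6 in the others. The fish oil conventional mice varied most from mouse to mouse: the median SD over 7284 well-measured genes was 0.211 on the log2 scale, against 0.119 in lard conventional, 0.112 in lard germ-free and 0.111 in fish oil germ-free mice. The clock genes Dbp and Arntl also differed among mice of a group. Dbp, which peaks in the day-night cycle when Arntl is low, lay between 10.36 and 11.34 in the lard conventional mice but between 7.44 and 11.14 in the fish oil conventional mice, and fish oil germ-free mice 5 and 6 (8.62 and 8.0) lay below the rest of their group (10.57 to 10.88).

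**Figure D1:**
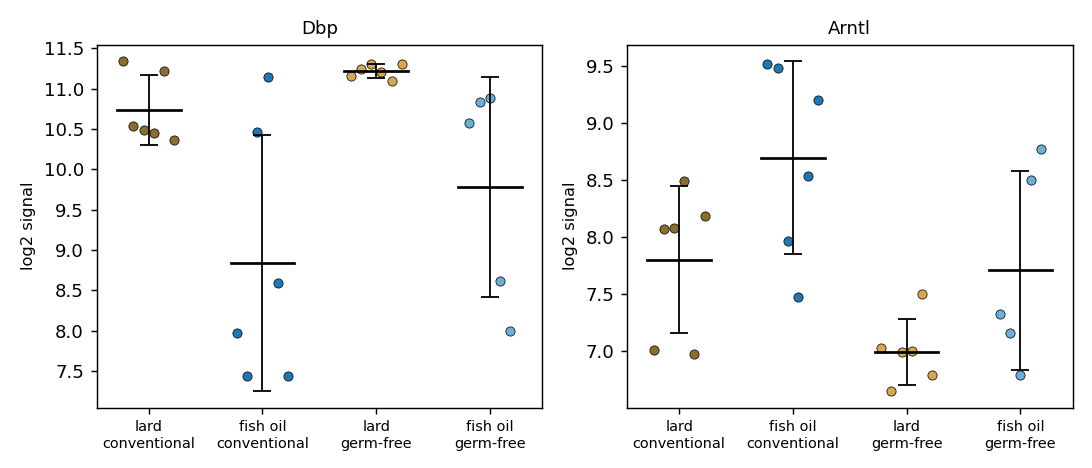
Log2 signal of the clock genes Dbp (left) and Arntl (right) in each liver of the 4 groups. Dots are mice, lines are group means and bars are the SD; Dbp spread from 7.44 to 11.14 in fish oil conventional mice and from 11.10 to 11.31 in lard germ-free mice.

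The first comparison asked how fish oil, set against lard, affected the liver of conventional mice. Of 19 measured genes of fatty acid synthesis, 3 fell on fish oil and 16 did not pass, and the list was lower by camera (adjusted p = 1.5e-10, and adjusted p = 0.314 with an estimated correlation). Thrsp, a lipogenic regulator, was 6.62-fold lower (log2 difference -2.73 ± 0.56), Fasn, the fatty acid synthase gene, 2.75-fold lower (-1.46 ± 0.33) and Elovl6, a fatty acid elongase gene, 2.11-fold lower (-1.07 ± 0.25). Mfsd2a, which encodes a transporter of lysophospholipids, fell 7.80-fold (-2.96 ± 0.58), Rgs16 6.61-fold, Lrtm1 2.83-fold and the apolipoprotein gene Apoa4 2.59-fold. In fish oil mice 3 and 4, whose clock indices (Dbp minus Arntl) of 2.49 and 3.66 lay within the lard range of 1.96 to 4.33, Mfsd2a (11.20 and 11.67), Rgs16 (12.08 and 12.30) and Apoa4 (12.65 and 13.27) lay within their lard ranges. In the other 4 fish oil mice they lay at 6.92 to 8.03, 7.60 to 8.59 and 10.67 to 11.91, below every lard mouse. With the clock index as a covariate the log2 differences were -1.74 for Mfsd2a, -1.37 for Thrsp, -1.15 for Rgs16 and -0.78 for Apoa4, and these calls were lost (adjusted p = 0.243, 0.287, 0.405 and 0.37). Every other call of this comparison was lost with that covariate as well. Among genes that rose were Serpina4-ps1 (2.91-fold), Adh6-ps1 (2.11-fold), Cyp4a31 of the fatty acid omega-hydroxylase family (1.93-fold), Malat1 (1.90-fold), Lpl, the lipoprotein lipase gene (1.81-fold), and Atxn1 (1.5-fold). Adjusted p-values of these genes lay between 0.0296 and 0.0452.

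Adjusted over the list alone, 14 of the 19 fatty acid synthesis genes fell, and the median was 1.70-fold lower. Of 23 genes of peroxisomal and omega oxidation, 3 rose, namely Cyp4a31, Ehhadh (0.42 ± 0.08 on the log2 scale) and Crot (0.37 ± 0.08). Adjusted over the list alone 6 rose and 3 fell, and the list was not shifted (adjusted p = 0.474). Of 19 circadian clock genes, 0 passed over all genes, while 2 were higher and 12 lower both at an unadjusted p under 0.05 in limma and adjusted over the list alone. The list was lower by camera (adjusted p = 1.52e-05, and adjusted p = 0.314 with an estimated correlation). Of 28 acute phase genes, 0 passed, 11 were higher at an unadjusted p under 0.05 in limma and 6 adjusted over the list alone. The list was higher by camera (adjusted p = 8.61e-07, and adjusted p = 0.332 with an estimated correlation). Marker lists were higher beside it, with 0 genes called in either. Of 15 neutrophil markers, 5 were higher at an unadjusted p under 0.05 in limma and 2 adjusted over the list alone (camera adjusted p 0.000968, and adjusted p = 0.332 with an estimated correlation). Of 20 Kupffer cell and macrophage markers, 3 were higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p 0.00771, and adjusted p = 0.583 with an estimated correlation). Mice 5 and 6 of the fish oil group carried Saa1, an acute phase gene, at 11.64 and 10.81. It lay at 6.03 to 7.61 in the other mice of that group and at 6.70 to 8.26 on lard. The acute phase list had a camera p as small in 28 of 100 splits of these mice, the real grouping among them. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, was 2.86-fold lower (adjusted p = 0.0547) and Cyp4a14 2.57-fold higher (adjusted p = 0.0583), and neither passed. Nor did the desaturase gene Scd1 (2.45-fold lower, adjusted p = 0.168), Cpt1a (1.17-fold lower, 0.286) or Sqle (1.45-fold higher, 0.439). The Scd1 signal on lard, 13.76 to 14.09, lay near the array maxima of 14.29 to 14.50, which limits every Scd1 fold given here. Its log2 difference was -1.29, but -0.75 without fish oil mouse 5 and -0.30 without mice 5 and 6. That of Cyp4a14 was 1.36, but 0.87 without lard mouse 1, where it passed (adjusted p = 0.0368, and 0.0337 to 0.409 over all alternatives for Cyp4a14).

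In all, limma called 161 genes, 41 higher and 120 lower, with 3301 at an unadjusted p under 0.05. In this comparison 14 of 36 lists were shifted by camera, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 5 by fry. Higher calls made up 25.5%, but 41.9% after a second quantile normalization, 15.5% with equal array medians and 58.8% with the 75th percentile of each array as a covariate (40 higher, 28 lower). The calls rested on the spread pooled over the groups and on single mice. Limma called 0 genes when the 2 groups were fitted alone (2827 at an unadjusted p under 0.05) or with the clock index as a covariate (1924), and 21 without mice 5 and 6 of the fish oil group. It called 282 genes above the median signal, 264 with equal array medians, 328 with array weights and 68 with the 75th percentile as a covariate. Leaving out 1 fish oil mouse gave 384 genes without mouse 1, 0 without mouse 2 (2560 at an unadjusted p under 0.05), 339 without mouse 3, 743 without mouse 4, 28 without mouse 5 and 1 without mouse 6. Leaving out 1 lard mouse gave 83 without mouse 1, 167 without mouse 2, 13 without mouse 4, and 0 without mouse 3, 5 or 6 (2829, 2918 and 2780 at an unadjusted p under 0.05).

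The second comparison set the same diets against each other in germ-free mice. Of 19 fatty acid synthesis genes, 17 were lower on fish oil and 2 did not pass, with a median of 2.60-fold. Thrsp fell 12.7-fold (-3.67 ± 0.59), Acacb 6.40-fold (-2.68 ± 0.35), Fasn 4.96-fold (-2.31 ± 0.35) and Acly, the ATP citrate lyase gene, 4.57-fold (-2.19 ± 0.30). Cholesterol synthesis fell as well, in 14 of 17 genes with a median of 1.88-fold. Among them were Sqle, the squalene epoxidase gene (4.66-fold, -2.22 ± 0.35), Msmo1 (3.12-fold), Lss (2.99-fold) and Hsd17b7 (2.06-fold). Other large falls were those of Cyp17a1 (10.2-fold), the lipid droplet genes Cidea (10-fold, -3.33 ± 0.71) and Cidec (9.55-fold, -3.26 ± 0.63), the apolipoprotein gene Apoa4 (9.98-fold, -3.32 ± 0.32) and Stap1. No fold is given for Stap1, whose signal of 4.56 to 5.53 on fish oil, against 7.78 to 8.77 on lard, lay near the 25th percentile of the arrays. The largest rise was that of Hsd3b5, a steroid dehydrogenase gene expressed mainly in male liver, at 24.6-fold (4.62 ± 0.59). On lard it lay at 6.12 to 6.81 in mice 1 to 4 but at 8.94 and 11.20 in mice 5 and 6, and the log2 difference was 5.32 without lard mouse 6 and 5.82 without mice 5 and 6 of both diets. Next came Serpina4-ps1 (9.35-fold), Gadd45g (6.88-fold), Myc (4.21-fold), Serpinb1a (3.97-fold) and Ugt2b37 (3.88-fold).

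Of 21 lipid droplet genes, 11 fell both over all genes and over the list alone, where 1 rose (camera adjusted p 5.97e-07, and adjusted p = 0.169 with an estimated correlation). Of 17 lipoprotein genes, 5 fell over all genes and over the list alone, where 1 rose, and the list was not shifted (camera adjusted p = 0.19). By camera the adjusted p of fatty acid synthesis was 9.11e-18 (adjusted p = 0.0715 with an estimated correlation), and adjusted over the list alone 18 of 19 genes fell. For cholesterol synthesis it was 3.16e-14 (adjusted p = 0.109 with an estimated correlation), and adjusted over the list alone 15 genes fell and 1 rose. Of 24 cell cycle genes, 17 fell and 22 fell adjusted over the list alone, including Ccnd1, the cyclin D1 gene (3.21-fold), and the replication genes Mcm6 (2.15-fold) and Mcm2 (1.99-fold). Camera gave an adjusted p of 3.16e-14, and an adjusted p = 0.109 with an estimated correlation. Of 19 male-biased liver genes, 12 rose and 15 rose adjusted over the list alone, among them the transporter gene Slco1a1 (3.00-fold) and Ugt2b38 (1.57-fold). Camera gave 1.03e-13, and an adjusted p = 0.0669 with an estimated correlation. Of 17 female-biased genes, 9 fell and 11 fell with 1 higher adjusted over the list alone (camera adjusted p 0.000441, and adjusted p = 0.158 with an estimated correlation). Of 19 markers of stellate cells and fibroblasts, 10 fell over all genes and over the list alone, including the collagen genes Col1a2 (1.77-fold), Col1a1 (1.74-fold) and Col3a1 (1.56-fold). Camera gave 2.32e-09, and an adjusted p = 0.0669 with an estimated correlation. Beside them, 4 of 11 cholangiocyte markers fell, Muc1 (-0.70), Epcam (-0.68), Krt19 (-0.38) and Krt7 (-0.25), with 4 lower and 1 higher adjusted over the list alone (camera adjusted p 0.0387, and adjusted p = 0.213 with an estimated correlation). Of 18 endothelial markers, Lyve1 (-0.93) and Eng (-0.44) fell, and 4 adjusted over the list alone (camera adjusted p 0.0224, and adjusted p = 0.629 with an estimated correlation). Of 22 genes of ER stress and the amino acid response, 8 rose, with 11 higher and 1 lower adjusted over the list alone, among them Creld2 (2.30-fold), Sdf2l1 (1.80-fold) and Ddit3 (1.48-fold). Camera gave 5.97e-07, and an adjusted p = 0.118 with an estimated correlation. Cpt1a, the carnitine palmitoyltransferase gene of mitochondrial fatty acid entry, fell 1.29-fold (adjusted p = 0.0304), while Cyp7a1 (1.01-fold higher, adjusted p = 0.988), Scd1 (2.41-fold lower, 0.0961) and Cyp4a14 (2.00-fold higher, 0.0738) did not pass.

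Limma called 2625 genes, 913 higher and 1712 lower, with 5020 at an unadjusted p under 0.05 and 14 of 36 lists shifted by camera, 0 with an estimated correlation (9 at an unadjusted p under 0.05) and 14 by fry. The direction of the whole set depended on scaling, since higher calls made up 34.8%, but 60.6% with equal array medians and 48% after a second quantile normalization. With the clock index as a covariate limma called 1575 genes, with log2 differences of -2.62 for Thrsp and -2.46 for Cidec. Without mice 5 and 6 of both diets it called 1432. The Cpt1a call was lost with that covariate (adjusted p = 0.247), with equal array medians (0.0772) and without those mice (0.315). It was also lost without fish oil mouse 2, 5 or 6 (0.0511, 0.0767 and 0.0673) or lard mouse 2, 4 or 5 (0.0539, 0.0709 and 0.0654).

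**Figure D2:**
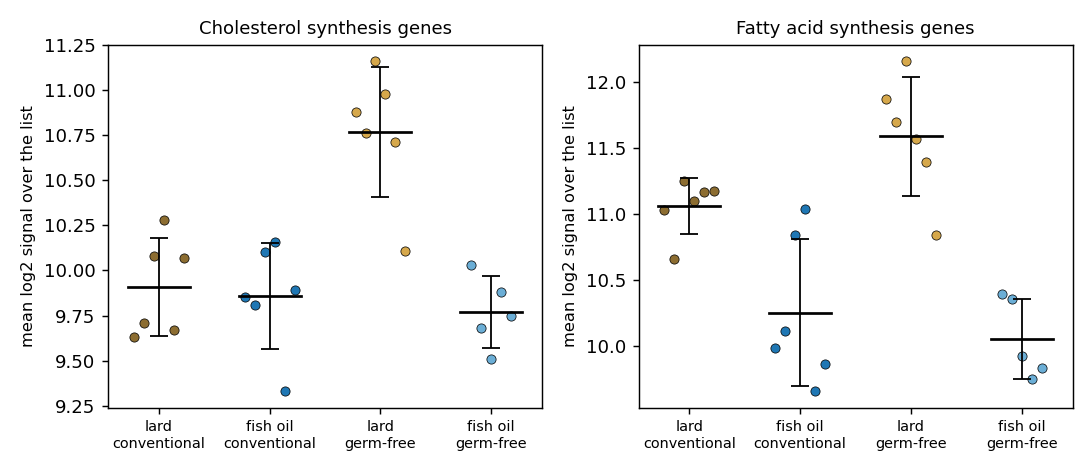
Mean log2 signal over the cholesterol synthesis genes (left) and the fatty acid synthesis genes (right) in each liver. Dots are mice, lines are group means and bars are the SD; the mean difference between germ-free and conventional mice on lard was 0.86 ± 0.17 (SE) for cholesterol synthesis, and that between fish oil and lard in germ-free mice was -1.53 ± 0.25 for fatty acid synthesis.

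The third comparison set germ-free against conventional mice on lard. The labels do not give the stock of the mice, so differences here and on fish oil may stem from stock as well as from bacterial status. Cholesterol synthesis genes rose in germ-free mice, where 11 of 17 were higher and 6 did not pass, with a median of 1.73-fold. Sqle (probe set 10424349) rose 7.06-fold (2.82 ± 0.34), Msmo1 2.26-fold (1.17 ± 0.21) and Mvd 2.06-fold (1.05 ± 0.19). All 6 germ-free mice had a Sqle signal above the highest conventional mouse (8.52 to 10.79 against 6.53 to 7.62). The mean over the cholesterol synthesis list was 10.71 to 11.16 in germ-free mice 1 to 5. In germ-free mouse 6 it was 10.11, within the conventional range of 9.63 to 10.28. Of 19 male-biased liver genes, 6 fell and 13 did not pass (camera adjusted p 5.53e-11, and adjusted p = 0.0835 with an estimated correlation). Among them, Hsd3b5 (probe set 10500545) fell 16.3-fold (-4.02 ± 0.56) and varied from 6.12 to 11.20 among germ-free mice and from 10.54 to 12.28 among conventional mice. Without germ-free mouse 6 the Hsd3b5 difference was -4.73. Slco1a1 (2.71-fold, -1.44 ± 0.25) and Gstp1 (1.48-fold) fell too. Of 20 markers of macrophages and of Kupffer cells, the resident macrophages of the liver, 5 fell, 2 rose and 13 did not pass (camera adjusted p 5.49e-08, and adjusted p = 0.214 with an estimated correlation). Vsig4 fell 1.98-fold (-0.98 ± 0.16), Timd4 1.67-fold and Clec4f 1.65-fold, while Itgax (0.41 ± 0.11 on the log2 scale) and Cx3cr1 (0.26 ± 0.06), which other mononuclear phagocytes also express, rose. The collagen genes Col1a1 (1.57-fold), Col1a2 (1.53-fold) and Col3a1 (1.48-fold) were higher. Other large rises were those of Lpin1 (3.36-fold), Atp6v0d2 (3.11-fold), Nipal1 (2.85-fold), Slc16a5 (2.81-fold) and Nrg4 (2.71-fold). Other large falls were those of Obp2a (4.72-fold), Cplane1 (2.66-fold), Fabp7 (2.51-fold) and Nnt, a mitochondrial transhydrogenase gene (2.42-fold, -1.27 ± 0.07). The Cplane1 fall came from 1 of its 3 probe sets, since the others differed by -0.08 and -0.06 on the log2 scale.

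The cholesterol synthesis list had an adjusted p of 4.9e-24 by camera and an adjusted p = 0.0388 with an estimated correlation, and adjusted over the list alone 14 of 17 genes rose. The female-biased list also passed with both settings of camera (camera 8.62e-08, adjusted p = 0.0388 with an estimated correlation). In it 2 of 17 genes were higher, Fmo2 (2.51-fold) and Sult1e1, and 9 adjusted over the list alone. No fold is given for Sult1e1, which lay at 3.73 to 4.43 in conventional mice, below the 25th percentile of every array, and at 7.46 in germ-free mouse 1 against 4.32 to 5.76 in the other germ-free mice. The cholangiocyte markers likewise passed with both settings (camera 6.69e-05, adjusted p = 0.0388 with an estimated correlation), with 1 of 11 higher, Epcam, and 3 adjusted over the list alone. Adjusted over the list alone, 9 male-biased genes fell, and 13 Kupffer cell and macrophage markers fell while 2 rose. Other lists were lower beside the Kupffer cell markers. Of 29 interferon response genes, 0 passed, 9 were lower at an unadjusted p under 0.05 in limma and 3 adjusted over the list alone (camera 2.61e-06, adjusted p = 0.289 with an estimated correlation). Of 18 endothelial markers, 0 passed over all genes or over the list alone, and 2 were lower at an unadjusted p under 0.05 (camera 0.00827, adjusted p = 0.539 with an estimated correlation). Of 10 genes of MHC class II presentation, 0 passed, 3 were lower at an unadjusted p under 0.05 and 2 adjusted over the list alone (camera 0.0275, adjusted p = 0.406 with an estimated correlation). Of 5 blood markers, Alas2 fell (-0.43), also over the list alone (camera 0.0246, adjusted p = 0.214 with an estimated correlation). Of 19 stellate cell and fibroblast markers, 4 rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell (camera 6.13e-07, adjusted p = 0.107 with an estimated correlation). Of 19 fatty acid synthesis genes, Acacb (2.52-fold) and Acss2 (2.08-fold) rose, with 4 higher and 1 lower adjusted over the list alone (camera 1.14e-06, adjusted p = 0.289 with an estimated correlation). Cyp7a1 was 2.68-fold higher with an adjusted p of 0.0524 and did not pass, and neither did Fasn (1.47-fold higher, 0.572), Scd1 (0.979), Cpt1a (1.14-fold higher, 0.555) or Cyp4a14 (1.57-fold higher, 0.49). The log2 difference of Cyp4a14 was 0.65, but 0.16 without lard conventional mouse 1.

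Limma called 363 genes, 226 higher and 137 lower, with 2428 at an unadjusted p under 0.05 and 19 of 36 lists shifted by camera, 3 with an estimated correlation and 8 by fry. Array weights gave 1084 genes and the 75th percentile of each array as a covariate 602. Leaving out 1 mouse gave 163, 225 and 217 genes without lard conventional mouse 2, 3 or 4 and 200 without lard germ-free mouse 4. The Acss2 call was lost without conventional mouse 2 (adjusted p = 0.0609). That of Nrg4 was lost without conventional mouse 2, 3 or 4 (0.0782, 0.0548 and 0.0646) or germ-free mouse 3 or 4 (0.0539 and 0.0573). That of Acacb was lost without conventional mouse 1, 2 or 3 (0.0761, 0.129 and 0.0557) or germ-free mouse 1, 2, 3, 4 or 5 (0.0858, 0.0843, 0.0968, 0.0849 and 0.0651). That of Sult1e1 was lost without conventional mouse 2, 3, 4 or 6 (0.129, 0.101, 0.106 and 0.0875) or germ-free mouse 2, 3 or 4 (0.111, 0.0555 and 0.0621).

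**Figure D3:**
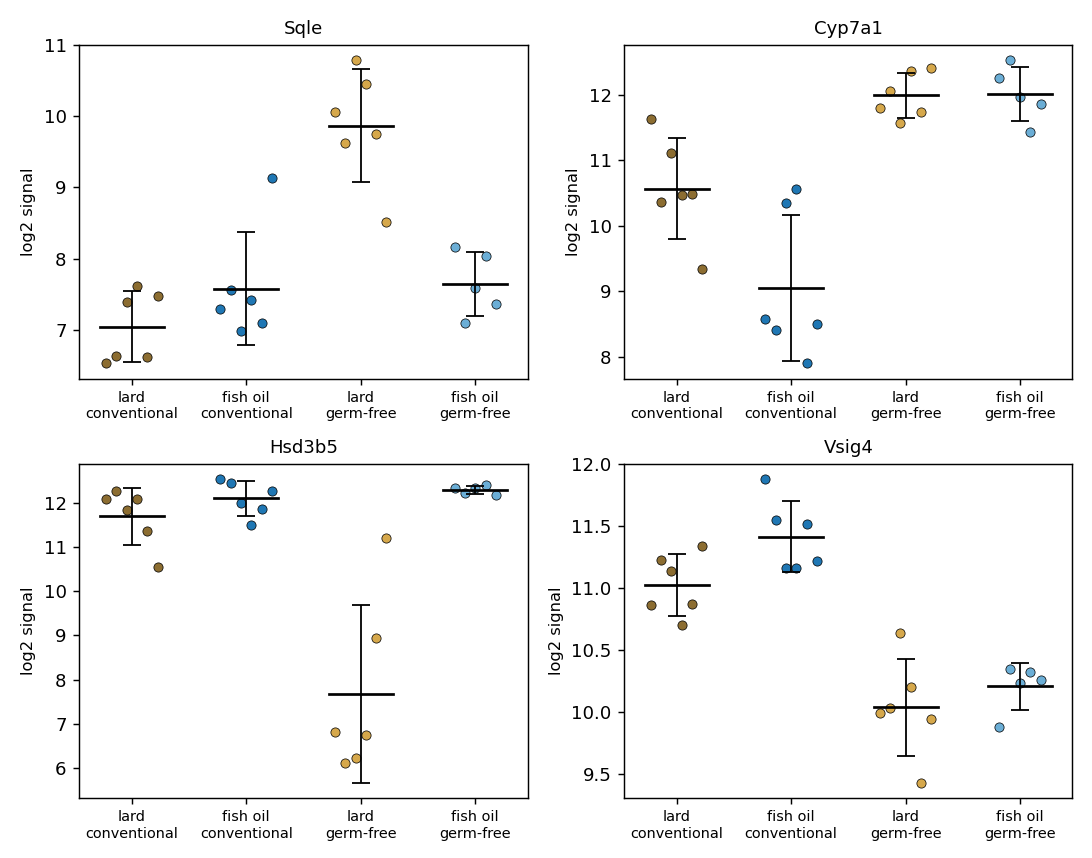
Log2 signal of Sqle, Cyp7a1, Hsd3b5 and Vsig4 in each liver of the 4 groups. Dots are mice, lines are group means and bars are the SD; Sqle was 7.06-fold higher in germ-free than in conventional mice on lard, and Cyp7a1 was 7.78-fold higher in germ-free than in conventional mice on fish oil.

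The fourth comparison set germ-free against conventional mice on fish oil. Of 17 genes of bile acid synthesis, 2 rose and 1 fell, and of 17 genes of bile acid transport and FXR signalling, 2 rose and 1 fell, and neither list was shifted (camera adjusted p = 0.157 and 0.228). Cyp7a1 (probe set 10511375) was 7.78-fold higher in germ-free mice (2.96 ± 0.40), at 11.43 to 12.53 in all 5 of them against 7.90 to 10.56 in conventional mice. In conventional mice 3 and 4, with clock indices of 2.49 and 3.66, it lay at 10.35 and 10.56, and in the other conventional mice at 7.90 to 8.58. Germ-free mice 5 and 6, with indices of 0.12 and -0.77, had 11.43 and 11.85. Nr0b2, a repressor of Cyp7a1, was 3.65-fold lower (-1.87 ± 0.33) and the oxysterol hydroxylase gene Cyp39a1 3.27-fold lower (-1.71 ± 0.31). Also higher were Serpinb1a (6.82-fold), Lpin1 (4.99-fold), Myc (4.56-fold), Pfkfb3 (4.27-fold) and the heat shock gene Hspa1a (4.08-fold, 2.03 ± 0.15). Of 20 Kupffer cell and macrophage markers, 9 fell, including Vsig4 (2.31-fold, -1.21 ± 0.16), C1qb (2.14-fold) and Clec4f (1.62-fold). Among conventional mice these were lowest in mice 3 and 4 (Vsig4 11.16 in both, C1qb 10.39 and 10.72, Clec4f 10.30 and 10.24), yet above every germ-free mouse. Among 18 endothelial markers 9 fell, including Clec4g (1.72-fold), Cdh5 (1.5-fold) and Gpr182 (1.42-fold). Of 29 interferon response genes, 9 fell, including Oasl2 (1.74-fold), Irf7 (1.62-fold) and Oasl1 (1.45-fold). Of 19 genes of glucose production and insulin response, 4 rose, including Igfbp1 (3.46-fold, 1.79 ± 0.31), Irs2 (1.96-fold) and Ppargc1a (1.66-fold).

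Camera gave an adjusted p of 2.62e-09 for the Kupffer cell markers and 2.61e-08 for both the interferon and the endothelial list, and each of these had an adjusted p = 0.391 with an estimated correlation. A camera p as small arose in 3, 11 and 12 of 100 splits for the Kupffer cell, interferon and endothelial lists, the real grouping among them. Adjusted over the list alone 12, 16 and 13 genes fell. Beside them, the MHC class II gene list, in which Cd86 (-0.54) fell of 10 genes (1 over the list alone), and the stellate cell and fibroblast markers, in which Colec11 (-1.14) and Pdgfrb (-0.52) fell of 19 (2 over the list alone), were lower by camera. Their adjusted p-values were 0.0198 and 0.0215, and both had an adjusted p = 0.508 with an estimated correlation. For glucose production and insulin response it gave 7.93e-06 (adjusted p = 0.0658 with an estimated correlation), with 9 genes higher and 1 lower adjusted over the list alone. Of 19 genes of mitochondrial fatty acid oxidation, Acadl (0.36 ± 0.06 on the log2 scale) and Eci1 (0.32 ± 0.07) rose, also over the list alone (camera 9.19e-05, adjusted p = 0.391 with an estimated correlation). Of 23 xenobiotic P450 genes, Cyp2b9 rose (3.30-fold) and 0 passed adjusted over the list alone (8 higher and 1 lower at an unadjusted p under 0.05 in limma; camera 9.19e-05, adjusted p = 0.391 with an estimated correlation). Further large falls were those of Arrdc3 (3.41-fold), Obp2a (3.23-fold), Apoa4 (3.03-fold) and Fabp7 (2.70-fold). Per1, a clock gene that also answers to fasting and glucocorticoids, was 3.31-fold higher, and the clock list was higher by camera (adjusted p = 0.00247, and adjusted p = 0.391 with an estimated correlation), with 2 of 19 genes higher both over all genes and over the list alone. Sqle (1.05-fold higher, adjusted p = 0.948), Fasn (1.23-fold lower, 0.704), Scd1 (1.09-fold higher, 0.931), Cpt1a (1.03-fold higher, 0.88) and Cyp4a14 (1.22-fold higher, 0.728) did not pass. Without fish oil conventional mice 5 and 6 the Scd1 difference turned to -0.868 (adjusted p = 0.0337).

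Limma called 1377 genes, 601 higher and 776 lower, with 4039 at an unadjusted p under 0.05 and 13 of 36 lists shifted by camera, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 6 by fry. Higher calls made up 43.6%, but 74.9% with equal array medians. Limma called 581 genes when the 2 groups were fitted alone and 2075 without conventional mice 5 and 6, where the log2 differences were 2.83 for Myc, -2.45 for Arrdc3 and 0.65 for Cyp2b9. Without fish oil germ-free mouse 1 there were 874 genes and without the averaged mice 3 and 4 there were 845. The Cyp2b9 call was lost without conventional mouse 5 or 6 (adjusted p = 0.0973 and 0.0775) or any 1 germ-free sample (0.062 to 0.0886). That of Obp2a was lost without conventional mouse 1 or 5 (0.0547 and 0.0533) or germ-free mouse 1 (0.0832).

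The last comparison tested whether the diet effect itself differed between germ-free and conventional mice. The diet effect on 6 of 17 cholesterol synthesis genes was more negative in germ-free than in conventional mice, where none of these 6 was called, with a list median of 1.93-fold. They included Sqle (6.74-fold, -2.75 ± 0.49), whose signal in lard germ-free mice was 9.87 ± 0.79 (SD, n = 6) against 7.05 to 7.65 as the means of the other groups. The collagen genes followed, since Col1a1 (-0.76 ± 0.15), Col1a2 (-0.71 ± 0.13) and Col3a1 (-0.61 ± 0.12) were lowered by fish oil in germ-free mice and not called in conventional mice. Hsd3b5 (18.5-fold, 4.21 ± 0.81), Serpinb1a (4.12-fold), Rnf186 (2.69-fold) and the heat shock genes Dnajb1 (2.90-fold) and Hspa1a (2.79-fold, 1.48 ± 0.21) had a more positive diet effect in germ-free mice. Cyp17a1 (5.54-fold), Apoa4 (3.86-fold), Cyp39a1 (3.70-fold), Prss8 (3.14-fold) and Pltp, the phospholipid transfer protein gene (2.86-fold), had a more negative one. Cplane1 (2.72-fold more positive) again rested on 1 probe set, the others differing by 0.19 and 0.06. Cyp7a1 (2.90-fold more positive, adjusted p = 0.22), Fasn (1.80-fold more negative, 0.501), Scd1 (1.02-fold, 0.995), Cpt1a (-0.14 on the log2 scale, 0.796) and Cyp4a14 (1.29-fold more negative, 0.853) did not pass.

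Camera gave an adjusted p of 1.74e-14 for cholesterol synthesis (adjusted p = 0.133 with an estimated correlation), with 13 genes lower adjusted over the list alone. For the stellate cell and fibroblast markers, of which 4 of 19 were called lower and 9 adjusted over the list alone, it gave 1.34e-08 (adjusted p = 0.112 with an estimated correlation). Of 11 cholangiocyte markers, Muc1 (-0.59) and Krt19 (-0.50) were called lower, and 4 adjusted over the list alone (camera 0.000169, adjusted p = 0.101 with an estimated correlation). Of 18 endothelial markers, 0 were called over all genes or over the list alone, and 5 were lower at an unadjusted p under 0.05 in limma (camera 0.000986, adjusted p = 0.552 with an estimated correlation). Limma called 121 genes, 43 higher and 78 lower, with 2426 at an unadjusted p under 0.05. By camera 12 lists were shifted, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 4 by fry. Higher calls made up 35.5%, but 76.5% with equal array medians, and the count ran from 24 to 233 as single mice were left out. It was 457 without fish oil conventional mice 5 and 6, 387 with the 75th percentile and 283 with the clock index as a covariate, 260 with array weights, 209 with 24 arrays, 79 with a trended robust variance and 40 with the mouse number as a block. Without lard germ-free mouse 6 the Hsd3b5 difference was 4.92. The Hsd3b5 call was lost without lard conventional mouse 2 (adjusted p = 0.0503) or lard germ-free mouse 1 (0.0526). Those of Apoa4, Cyp17a1, Cyp39a1, Prss8, Rnf186, Cplane1 and Serpinb1a were lost on leaving out any of at least 10 of the 23 samples.

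Across the 2 kinds of mice, 88 genes were called for diet in both and in the same direction, 18 higher and 70 lower, against 1.88 and 10.3 for independent lists, and 0 were called in opposite directions. The 2 diet comparisons share no arrays, but they and the 2 status comparisons use the same pooled spread per gene. Genes of low spread are thus favoured in each, so the counts for independent lists may be too low. With the clock index as a covariate limma called 0 genes in both diet comparisons, since it called 0 in conventional mice (1924 at an unadjusted p under 0.05). The shared count was 155 above the median signal, 48 without germ-free mice 5 and 6, 35 with the 75th percentile as a covariate and 3 without fish oil conventional mice 5 and 6. Across the 2 diets, 92 genes were called for bacterial status in the same direction, 31 higher and 61 lower, against 6.81 and 5.33 for independent lists, and 2 in opposite directions. That count was 55 with the clock index as a covariate and 57 without germ-free mice 5 and 6. The fold changes correlated across genes, which are not independent replicates, at r = 0.58 for diet and r = 0.355 for status. In other splits of the same mice camera shifted a median of 10, 7, 10, 7 and 9 lists in the 5 comparisons. Only for germ-free against conventional mice on lard did few splits reach the real list count.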

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

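The tests of the cholesterol synthesis list against matched lists and against a difference between mouse stocks, and both tests on Nnt, were chosen only after the results were seen, as were the fits with the clock index and without fish oil conventional mice 5 and 6.

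Cholesterol synthesis genes were higher in germ-free than in conventional mice on lard, by a mean of 0.86 ± 0.17 on the log2 scale. Of 10000 random lists matched on signal level, 0 reached the median of the list, which argues against a shift shared by genes of like brightness. The mean difference stayed at 0.86 ± 0.18 with the clock index as a covariate. That fit takes 1 slope for all groups, so it decides little by itself. Lard conventional mice 1 and 5 had indices of 4.33 and 4.24, within the lard germ-free range of 3.6 to 4.59. Their list means of 9.63 and 9.67 lay below every lard germ-free mouse (10.11 to 11.16), which argues against clock phase. The mean difference was -0.09 ± 0.18 on fish oil, a change of -0.95 ± 0.24, which argues against a fixed difference between mouse stocks. A stock difference that depends on diet and an effect of bacterial status on sterol synthesis both stay open, and the rise may reflect the latter.

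Fatty acid synthesis genes were lower on fish oil in conventional mice by a mean of -0.81 ± 0.24. With the clock index as a covariate the difference was -0.43 ± 0.24. Diet and clock index moved together in fish oil mice 1, 2, 5 and 6. Mice 3 and 4 had indices within the lard range (2.49 and 3.66). Their list means of 10.84 and 11.04 lay within the lard range of 10.66 to 11.25. The other fish oil mice lay at 9.66 to 10.12, below every lard mouse. With only mice 3 and 4 at lard-like indices, an effect of diet and a difference in clock phase cannot be told apart in these mice. Without fish oil mouse 3 the mean difference was -0.93 ± 0.24 and without mice 5 and 6 it was -0.57 ± 0.24, so a contribution of aberrant livers is likewise undecided. In germ-free mice the difference was -1.53 ± 0.25, and -1.24 ± 0.23 with the clock index. Among germ-free mice 1 to 4, a subset chosen after the results were seen, it was -1.60 ± 0.20. Their clock indices were near each other, at 3.24 to 4.09 on fish oil and 4.12 to 4.59 on lard. In germ-free mice these values argue against clock phase as the whole account of the lowering. A lowering by fish oil may hold in both kinds of mice, as a hypothesis, but part of it could be clock phase.

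Nnt was lower in every germ-free than in every conventional mouse, with a gap of 0.58 between the nearest values and a difference of 0 ± 0.10 between its germ-free effects on the 2 diets. A fixed difference between mouse stocks has the values it needs, and Nnt is known to differ between C57Bl/6 substocks. An effect of bacterial status cannot be told apart from it, because the labels do not give the stock of the mice. Nnt included, 17 genes were lower and 13 higher in every germ-free mouse, against 0.029 expected by chance, including Wdfy1 (-1.18 on lard, -1.02 on fish oil), Nbea (-0.93 and -1.11), Fabp7 (-1.33 and -1.43) and Tmem267 (1.17 and 1.04).

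The real grouping is counted among the 100 splits and among those as large, so that 1 split as large is the real one alone. The 161 genes called for diet in conventional mice were reached in 2 of 100 splits (highest other 417). The 1377 called for status on fish oil were also reached in 2 (highest other 1942). In both, another split gave more genes, so chance is unlikely but cannot be excluded. The 2625 called for diet in germ-free mice and the 363 for status on lard were reached by the real grouping alone (highest other 1467 and 21). So were the 121 genes with a different diet effect (highest other 12). Those splits shuffled bacterial status within each diet, which also mixed the status effects into the spread. They therefore do not test the difference of the diet effects alone. For the 88 and 92 shared genes the highest other was 0. Splits of each single comparison called a median of 0 genes, so shared genes could hardly arise, and the splits do not test the sharing. For list counts chance is unlikely for status on lard, though not excluded (19 lists, 3 splits as large, highest other 19). Splits as large were more frequent for diet in conventional mice (14 lists, 22 splits, highest other 23) and diet in germ-free mice (14, 11 splits, highest other 19). The same held for status on fish oil (13, 17 splits, highest other 24) and the difference of the diet effects (12, 24 splits, highest other 17). Chance stays open as the account of all these list counts. Single lists differed in this. For diet in germ-free mice the real grouping alone reached the camera p of fatty acid synthesis, cholesterol synthesis and the stellate cell markers. That of the endothelial markers was reached in 19 splits. For status on lard the splits numbered 2 for cholesterol synthesis, 4 for Kupffer cell markers, 39 for endothelial markers and 44 for MHC class II. For status on fish oil they numbered 20 for the P450 list and 20 for the clock list. The splits with 417 and 1942 genes point to a structure of the samples. Their 2 parts had mean clock indices of 2.83 and 0.24, and of 2.6 and -0.88. They differed in other ways too, since the split with 417 put 4 lard and 2 fish oil mice against the reverse, and that with 1942 put mice 5 and 6 of both fish oil groups in the same part. Which of these features counts was not tested.

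Single mice lay far from the rest of their group for 18 of 328 groups of named genes, and chance places about 1 in 20 groups there. In lard conventional mice these were mouse 1 for Cplane1 (7.94, others 8.66 to 8.97), Cyp4a14 (9.48, others 12.06 to 12.82) and Cyp4a31 (9.38, others 10.53 to 11.22), mouse 2 for Fasn (11.74, others 12.51 to 12.81) and Lss (8.70, others 9.13 to 9.32), and mouse 5 for Arrdc3 (11.26, others 12.04 to 12.29) and Atxn1 (8.88, others 9.27 to 9.50). In fish oil conventional mice they were mouse 1 for Fabp7 (10.97, others 9.18 to 9.78) and Serpinb1a (8.22, others 6.20 to 6.89), mouse 4 for Cidea (9.78, others 5.31 to 6.15) and Prss8 (8.48, others 6.44 to 7.20), and mouse 6 for Clec4g (10.54, others 11.46 to 11.86) and Sqle (9.13, others 6.98 to 7.56). In lard germ-free mice they were mouse 6 for Hsd17b7 (10.70, others 11.29 to 11.59) and mouse 3 for Nipal1 (9.49, others 7.26 to 8.03). In fish oil germ-free mice they were the averaged mice 3 and 4 for Atxn1 (9.87, others 9.21 to 9.35) and Dnajb1 (11.22, others 9.60 to 10.01), and mouse 1 for Vsig4 (9.88, others 10.23 to 10.35).

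By the test of the difference, 18 of 82 named genes had a diet effect that differed between germ-free and conventional mice. On the log2 scale it was more negative in germ-free mice for Sqle (-2.75), Cyp17a1 (-2.47), Apoa4 (-1.95), Cyp39a1 (-1.89), Prss8 (-1.65), Pltp (-1.52), Msmo1 (-1.41), Lss (-1.25), Hsd17b7 (-0.78), Col1a1 (-0.76), Col1a2 (-0.71) and Col3a1 (-0.61). It was more positive for Hsd3b5 (4.21), Serpinb1a (2.04), Dnajb1 (1.53), Hspa1a (1.48), Cplane1 (1.45) and Rnf186 (1.43). The naming rule itself took the highest and lowest called genes of this test. The share of 18 in 82 therefore cannot show how common such differences were. Among all 19938 genes tested, 121 were called.

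Among 13767 probe sets paired with no gene or with several, which the comparisons above did not use, limma called 59 for diet in conventional mice (50 higher, 9 lower), 696 for diet in germ-free mice (540 higher, 156 lower), 34 for status on lard (25 higher, 9 lower), 130 for status on fish oil (72 higher, 58 lower) and 4 for the difference of the diet effects (1 higher, 3 lower).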

How the results depend on the processing

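The fits with 24 arrays, the clock index, the 75th percentile and without mice 5 and 6 were chosen only after the results were seen. For each change below the cause was not tested, except that a fold threshold of 1.5, a filter on level or fewer mice alter the number of genes or samples by construction.

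Of 1312 differences of named genes under alternatives other than leaving out 1 mouse, 1204 stayed on their side of the threshold. The others were 86 that no longer passed, 21 that newly passed and 1 that reversed. A reversal was counted only where the gene was called with or without the alternative, so small uncalled differences may also have changed sign. Of 1693 on leaving out 1 mouse, 1443 stayed on their side, 245 no longer passed and 5 newly passed. The reversed one was Scd1 for status on fish oil, at -0.868 ± 0.26 (adjusted p = 0.0337) without fish oil conventional mice 5 and 6.

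Genes called for diet in conventional mice (161) numbered 282 above the median signal, 264 with equal array medians, 328 with array weights, 34 at 1.5-fold, 68 with the 75th percentile, 21 without mice 5 and 6, 0 with the clock index (1924 at an unadjusted p under 0.05 in limma) and 0 in the 2 groups alone (2827). Those for diet in germ-free mice (2625) numbered 681 at 1.5-fold, 1575 with the clock index and 1432 without germ-free mice 5 and 6. Those for status on lard (363) numbered 1084 with array weights, 602 with the 75th percentile and 158 at 1.5-fold. Those for status on fish oil (1377) numbered 332 at 1.5-fold, 581 in the 2 groups alone and 2075 without fish oil conventional mice 5 and 6. Genes with a different diet effect (121) numbered 79 with a trended robust variance, 260 with array weights, 73 at 1.5-fold, 40 with the mouse number as a block, 209 with 24 arrays, 283 with the clock index, 457 without fish oil conventional mice 5 and 6 and 387 with the 75th percentile. Over all numbers, 33 pairs of samples with the same mouse number had a mean r of 0.0397 (-0.403 to 0.42) against -0.00814 for other pairs, but numbers 5 and 6 shared a low 75th percentile (8.422 to 8.436) in both germ-free groups, so the number is not free of structure.

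The 88 genes shared by the diet comparisons became 155 above the median signal, 25 at 1.5-fold, 0 with the clock index (limma), 3 without fish oil conventional mice 5 and 6, 35 with the 75th percentile and 48 without germ-free mice 5 and 6. The 92 shared for status became 49 at 1.5-fold, 55 with the clock index and 57 without germ-free mice 5 and 6. Lists shifted by camera fell from 14 to 5 by fry, 9 with the clock index and 0 with an estimated correlation for diet in conventional mice, and from 14 to 0 with it in germ-free mice. For status they fell from 19 to 8 by fry and 3 with an estimated correlation on lard, and from 13 to 7 above the median signal, 6 by fry and 0 with an estimated correlation on fish oil. For the difference of the diet effects they fell from 12 to 4 by fry and 0 with an estimated correlation. At an unadjusted p under 0.05 the estimated correlation gave 5, 9, 8, 2 and 5 lists.

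Leaving out 1 mouse, the counts ran from 0 to 743 for diet in conventional mice, 1989 to 2609 in germ-free mice, 163 to 459 for status on lard, 845 to 1668 on fish oil, 24 to 233 for the difference, 0 to 383 for shared diet genes and 42 to 128 for shared status genes, and lists 12 to 17, 13 to 17, 16 to 20, 12 to 18 and 9 to 16. The count of 0 for diet in conventional mice arose without fish oil conventional mouse 2 (2560 at an unadjusted p under 0.05 in limma) and without lard conventional mouse 3, 5 or 6 (2829, 2918 and 2780). The difference count was 73, 35 and 206 without fish oil conventional mouse 3, 4 or 6, and 41, 63, 49, 38 and 44 without fish oil germ-free mouse 1, 2, 3 with 4, 5 or 6. It was 44, 25, 67 and 40 without lard conventional mouse 1 to 4, and 24, 39, 31, 29, 68 and 233 without lard germ-free mouse 1 to 6. The shared diet count was 148, 0, 188, 383, 11 and 0 without fish oil conventional mouse 1 to 6. It was 45, 0, 8, 0 and 0 without lard conventional mouse 1, 3, 4, 5 or 6, and 56 and 58 without lard germ-free mouse 2 or 4. The shared status count was 42, 53 and 60 without lard conventional mouse 2, 3 or 6 and 57 without lard germ-free mouse 4 or 5.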

Other observations

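The genes discussed in this part were chosen only after their values were seen, apart from members of the gene lists, and so was the comparison of germ-free mice 1 to 4 with mice 5 and 6. In germ-free mice on fish oil 3 heat shock genes, a group for which no list was tested, were higher than on lard. Hspa1a, which encodes the inducible HSP70 chaperone, was 3.04-fold higher, Dnajb1, its cochaperone gene, 2.45-fold and Hsph1 2.63-fold. Against conventional mice on fish oil they were 4.08-fold, 3.92-fold and 3.10-fold higher. Dnajb1 and Hspa1a were higher in every germ-free than in every conventional mouse, by gaps of 0.21 and 0.06.

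Of 12 genes that make polyunsaturated fatty acids, 7 fell on fish oil in germ-free mice, including the desaturase and elongase genes Fads1 (-1.45), Elovl5 (-1.30) and Fads2 (-1.15 on the log2 scale), and 8 fell adjusted over the list alone (camera adjusted p 1.57e-06, and adjusted p = 0.0669 with an estimated correlation). In conventional mice 1 fell, Fads6 (-0.35), and 5 adjusted over the list alone (camera adjusted p 0.00102, and adjusted p = 0.314 with an estimated correlation).

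Fish oil conventional mice 5 and 6 had Lcn2 signals of 13.17 and 13.16 beside their Saa1 signals of 11.64 and 10.81. The clock index, Dbp minus Arntl, of fish oil conventional mice 1 to 6 was -1.55, -2.04, 2.49, 3.66, 0.05 and -1.76. That of fish oil germ-free mice was 3.24, 3.67, 4.09 for the averaged mice 3 and 4, 0.12 and -0.77. It lay between 1.96 and 4.33 in lard conventional mice and between 3.6 and 4.59 in lard germ-free mice.

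The 75th percentile of the arrays of germ-free mice 5 and 6 of both diets lay between 8.422 and 8.436, and that of the other germ-free arrays at 8.511 or above. For fish oil against lard, the mean cholesterol synthesis difference was -1.20 ± 0.16 in germ-free mice 1 to 4 and -0.59 ± 0.31 in mice 5 and 6, and that of fatty acid synthesis -1.60 ± 0.20 and -1.32 ± 0.28.

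Of the 36 lists, 8 were shifted by camera in 0 of the 5 comparisons: Toll-like receptor signalling, bile acid synthesis, bile acid transport, cholesterol efflux, other PPAR-alpha targets, and the markers of hepatocytes, lymphocytes and pancreas.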
